A study of Mus musculus with 6 samples.

How the data were processed

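Total RNA of infarct tissue from 3 Irf3 knockout and 3 wild-type male mice, taken 4 days after coronary ligation, was sequenced, per the labels. The labels give each library a genotype and a replicate number and do not say whether a number is shared between genotypes. They give the strain for the wild type, and the strain of the knockout mice is not given in the sources used here. The table the authors deposited holds RPKM, reads scaled to gene length in kb and to library depth, rounded to 2 decimals, with a length for each gene. Per the submitters' processing notes the tools were Picard 1.100, STAR 2.3.0, SAMtools 0.1.18.0, HTSeq 0.6.0 and edgeR 3.8.6, and the genome build was NCBIM37 (mm9). Their settings, the handling of reads that map to several places, strand and the filter behind the 12969 genes are not given in the sources used here. A gene that shares sequence with a copy can gain or lose reads through these settings.

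Columns were matched to samples by name. In 5 lines part of the gene name had moved into the first value cell, and these were repaired. Some symbols had been turned into dates by a spreadsheet, and these were left as they are. Ifnb1, the lymphocyte genes beyond 5 of the list of 25 and other genes of the lists that the table does not hold are not analysed here.

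The depth of each library was taken from the steps between low RPKM values multiplied by gene length, which lie 1 read apart. It came to 14.8 to 61.9 M reads in genes, and 100% of the 113 to 302 low values used per library fell within 0.2 reads of a whole number, where chance gives 40%. On 3 simulated libraries the estimate was off by at most 0.014%. Rounding to 2 decimals left an error under 0.5 reads for 19.3% of genes in the deepest library and for up to 84.8% in the others, so whole reads were not recovered for all genes and no negative binomial count test was run.

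Genes with a mean of at least 1 RPKM over the 6 libraries were tested on log2(RPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a mean-variance trend, two-sided), knockout against wild type, with Benjamini-Hochberg adjustment over the 12913 genes and a threshold of 0.05. Fold changes in log2 are on this scale, which understates the change of genes with low values. Folds named as such are ratios of mean RPKM. Because nothing in the labels says more of the 3 animals per group, p-values measure the spread between these samples. With 3 against 3 an exact permutation test of a single gene cannot go below p = 0.1, and the adjusted p-values rest on limma's model.

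Before the data were examined 22 gene lists were fixed: interferon-stimulated genes, interferon-gamma and antigen presentation, nucleic acid sensing and interferon signalling, inflammatory cytokines and chemokines, matrix metalloproteinases and inhibitors, fibroblast and extracellular matrix, cardiomyocyte, fatty acid oxidation and oxidative phosphorylation, monocyte and macrophage, neutrophil, lymphocyte, dendritic cell, endothelial, smooth muscle and pericyte, mesothelial and epicardial, cell cycle, hypoxia and glycolysis, immediate early and stress, red cell and platelet, skeletal muscle, adipocyte, and genes near Irf3. The 21 lists with at least 5 tested members were tested with camera (limma) at a preset correlation of 0.01, adjusted over the lists. Camera compares a list with all other genes, and 12 lists were called. With the correlation estimated for each list 0 lists were called and 1, interferon-stimulated genes, had an unadjusted p under 0.05 (0.0316), and with fry 0 lists were called after adjustment and 2 had an unadjusted p under 0.05, which was 0.0026 for interferon-stimulated genes and 0.0273 for the interferon-gamma list.

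Named genes were chosen by a rule set before the data were examined: Irf3, Bcl2l12, Ifnb1, Isg15, Ifit1, Irf7 and Cxcl10; the 10 genes with the largest fold change in each direction among those called with groups that do not overlap, passing over predicted or unnamed symbols (23 of the 65 called genes); and the 3 members of each tested list with the smallest p. Fewer than 10 named genes rose. Other genes named in the report were chosen after their values were seen, to show members of a list, copies of named genes, or members called over a list alone.

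The fit was tested on simulated data with the real genes' means, residual spread (at most 1 on the log2 scale) and depths for the comparison of knockout with wild type. Over 12913 genes it called 77 of 100 genes changed 4-fold and 20 of 100 changed 2-fold, with 2 false calls. A list lowered by 1 on the log2 scale was called, and 0 of 20 other lists were. The simulated noise was independent between genes. The simulation therefore cannot show how often camera calls unchanged lists whose genes vary together.

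GC content, chromosome and gene order came from GENCODE M21 and RefSeq annotation of GRCm38, matched by symbol or by a synonym that names 1 gene. GC content was found for 98.4% and a chromosome for 97.8% of the genes. Since the table uses another build, no coordinates are given. Copies were found with blastn (BLAST 2.17.0) between the longest transcripts of the genes in the table, at 95% identity or more over at least 200 bases, and CPM, taken as RPKM times gene length in kb, were summed over a gene and its copies. Neighbours whose transcripts overlap are found as well. Fisher's exact test, Spearman correlations and exact binomial intervals used SciPy 1.17.1 in Python 3.11.15.

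Alternatives were other pseudocounts and filters, quantile normalization, scaling to equal sums or by the median of ratios, limma without the trend, array weights (estimated gene by gene, since the REML estimate did not converge), a replicate block, each library left out, another threshold, estimated correlations and fry. Chosen after seeing the data were limma-voom on reads estimated from RPKM, length and depth, the same without knockout replicate 2, array weights on the other splits of the libraries, and a loess correction for GC content and length (span 0.5).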

Results

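RNA-seq was measured in infarct tissue of male mice 4 days after permanent ligation of the left anterior descending coronary artery. The 6 libraries fell into 2 groups of 3, mice lacking Irf3 and wild-type mice, all about 12 weeks old. Irf3 encodes a transcription factor that switches on type I interferon and other antiviral genes once nucleic acid sensors are engaged, and the comparison asks which transcripts of the healing infarct depend on it. Values were RPKM for 12969 genes, of which 12913 had a mean of at least 1 RPKM and were tested. The steps between low values gave 14.8, 18.1 and 61.9 M reads in genes for knockout replicates 1 to 3 and 18.9, 20.8 and 15.7 M reads for wild-type replicates 1 to 3. Knockout replicate 2 stood apart: its mean correlation with the other 5 libraries was 0.907, against 0.941 to 0.966 for the others, and it took the far end of the first principal component, which held 65.4% of the variance. Lars2, a locus that also collects ribosomal RNA reads in many mouse libraries, held 2.48% of the reads there and 0.132% to 0.701% in the other libraries. For that reason counts of called genes and lists, and counts over a list alone that differ, are also given without that library. A typical gene also read lower there, with a median-of-ratios factor on RPKM of 0.817, against 1.024 to 1.085 in the other libraries. The medians of lists given per library are not corrected for this.

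The knocked-out gene was lower in every knockout library but was still read. Irf3 stood at 7.4, 8.74 and 7.68 RPKM in the knockout libraries and at 13.76, 13.87 and 11.56 RPKM in the wild type, a log2 fold change of -0.65 ± 0.18 (SE, n = 3 per group) that did not pass the test across genes (limma adjusted p = 0.344). Bcl2l12, the head-to-head neighbour of Irf3, stood at 0.75, 0.25 and 1.32 RPKM against 3.40, 3.16 and 2.16 RPKM, a log2 fold change of -1.17 ± 0.26 (limma adjusted p = 0.15). Which part of Irf3 was deleted is not given in the sources used here, so reads from the rest of the gene can remain. The 35 tested genes of the list of Irf3 neighbours had a median log2 fold change of 0.28 (camera adjusted p = 0.00132; adjusted p = 0.717 with an estimated correlation). None of the 35 was called over all genes or adjusted over the list alone (4 had an unadjusted limma p under 0.05), Dhdh and Cpt1c standing at -0.68 ± 0.23 and -0.47 ± 0.19 (adjusted p = 0.513 and 0.556). Knockout replicate 2 gave the list its highest value, 0.61, and without that library the median was 0.06 (adjusted p = 0.565).

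Interferon-stimulated genes were the group that separated the genotypes most. All 50 genes of the list fixed for them were tested: 19 fell in the knockout, none rose, and adjusted over the list alone 48 fell. The list had a median log2 fold change of -1.36, and 49 of its 50 members had a value below 0. Isg15, a ubiquitin-like protein attached to other proteins during the antiviral response, fell 5.94-fold, from 44.9 ± 7.11 to 7.56 ± 1.26 RPKM (SD, n = 3 per group), which is -2.42 ± 0.21 (SE) on the log2 scale (limma adjusted p = 0.00227). Ifit3 and Ifit1, which bind viral RNA, fell 7.76-fold and 7.23-fold (adjusted p = 0.0029 and 0.00719). Irf7, the transcription factor that amplifies interferon production, fell 6.15-fold (adjusted p = 0.00367). Genes of the Oas family, sensors of double-stranded RNA, fell as well, with Oasl2 at 5.13 ± 1.69 against 29.1 ± 4.88 RPKM (adjusted p = 0.00846) and Oas3 at 0.50 ± 0.079 against 5.14 ± 2.20 RPKM (adjusted p = 0.0148). Mx1, Rsad2, Usp18, Zbp1 and Rtp4 also fell. Bst2, which did not pass over all genes, had a log2 fold change of -1.40 ± 0.29 (adjusted p = 0.129). Xaf1 was the only member with a value above 0, at 0.51 ± 0.32 (adjusted p = 0.556), and Ifitm3 was at -0.37 ± 0.28 (adjusted p = 0.573). Ifnb1, the gene of interferon beta, is not analysed here.

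The set test called the interferon-stimulated list (camera adjusted p = 1.43e-44), but not with the correlation between its genes estimated from the data (adjusted p = 0.661 with an estimated correlation). Relative to the wild-type mean, the list's median was -1.18, -1.91 and -1.14 in knockout replicates 1 to 3 and between -0.06 and 0.08 in the wild-type libraries. Without knockout replicate 2, 27 members fell, the median was -1.11 (camera adjusted p = 6.74e-66; adjusted p = 0.066 with an estimated correlation), and adjusted over the list alone 46 fell and Xaf1 rose. Isg15, Ifit3 and Irf7 were called whichever library was left out, and the other 16 of the 19 lost their call in at least 1 of these fits. Without wild-type replicate 3 the adjusted p was 0.0634 for Ifit1, 0.0786 for Ifi44, 0.0774 for Oas3 and Oasl2, 0.143 for Mx1, 0.092 for Rsad2, 0.111 for Usp18 and Zbp1 and 0.138 for Rtp4.

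**Figure D1:**
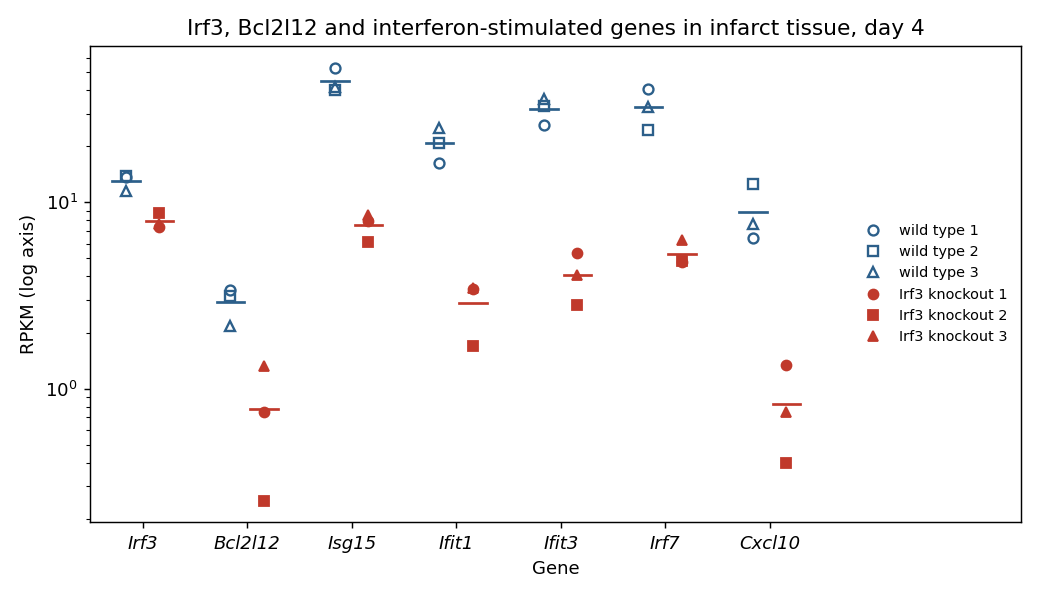
RPKM on a log axis of Irf3, Bcl2l12 and 5 interferon-induced genes in each of the 6 libraries, with open blue symbols for wild type, filled red symbols for the Irf3 knockout and a bar at each group mean. For each gene shown all knockout libraries lie below all wild-type libraries; Isg15 averages 7.56 RPKM in the knockout and 44.9 RPKM in the wild type.

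Genes of the interferon-gamma response and antigen presentation were lower as a list, and its members differed. Of 31 tested, Ifi47, an interferon-inducible GTPase, fell from 10.2 ± 0.58 to 2.17 ± 1.07 RPKM (SD, n = 3 per group; log2 fold change -1.88 ± 0.28, limma adjusted p = 0.0329), and 14 fell adjusted over the list alone. Irgm1 and Irgm2, GTPases of the same family, had log2 fold changes of -1.61 ± 0.28 and -1.67 ± 0.30 (adjusted p = 0.0707 and 0.0777). Of antigen presentation genes, H2-K1 and Tap1, of the class I pathway, were among the 14, at -0.87 ± 0.27 and -0.68 ± 0.19 (adjusted p = 0.439 and 0.35 over all genes). B2m and H2-D1 of the same pathway did not pass over the list alone, at -0.70 ± 0.33 and -0.64 ± 0.30 (adjusted p = 0.556 each). For both, all knockout libraries lay below all wild-type libraries. Among the others that did not pass were Cd74, H2-Ab1 and H2-Eb1 of the class II pathway at -0.02 ± 0.28, 0.05 ± 0.31 and -0.15 ± 0.30 (adjusted p = 0.971, 0.941 and 0.81). Tap2, Psmb8 and Psmb10 did not pass either, at -0.17 ± 0.19, -0.18 ± 0.21 and 0.06 ± 0.19 (adjusted p = 0.666, 0.677 and 0.89). The list's median was -0.64 (camera adjusted p = 4.41e-09; adjusted p = 0.717 with an estimated correlation). Its medians relative to the wild-type mean were -0.43, -0.76 and -0.59 in knockout replicates 1 to 3. Without knockout replicate 2, 6 members fell, and 13 fell adjusted over the list alone, H2-K1 no longer among them. The median was then -0.54 (camera adjusted p = 1.47e-13, and 0.711 with an estimated correlation). Without wild-type replicate 1 the median was -0.38 (camera adjusted p = 4.21e-05). Ifi47 had an adjusted p of 0.196 without wild-type replicate 3.

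Among inflammatory cytokines and chemokines, Cxcl10, a chemokine for T cells that interferon induces, fell 10.7-fold, from 8.86 ± 3.21 to 0.827 ± 0.470 RPKM (SD, n = 3 per group; limma adjusted p = 0.011, and 0.0774 without wild-type replicate 3). It was the only one of 24 tested members called over all genes, and adjusted over the list alone 2 fell. The other was Ccl12, a monocyte chemoattractant, at 13.8 ± 2.10 against 27.6 ± 3.38 RPKM (adjusted p = 0.118 over all genes). Ccl5 was at 1.63 ± 0.415 against 4.597 ± 2.28 RPKM (adjusted p = 0.404). The list's median was -0.35 (camera adjusted p = 0.0406; adjusted p = 0.829 with an estimated correlation). It was -0.81 in knockout replicate 2 relative to the wild-type mean and 0.0083 and -0.20 in the other 2 knockout libraries. The list was not called without knockout replicate 2 (median -0.11, adjusted p = 0.189) or without wild-type replicate 1 (median -0.09, adjusted p = 0.464). Il1rn, the interleukin-1 receptor antagonist, rose adjusted over the list alone without knockout replicate 2 (log2 fold change 1.63 ± 0.40, adjusted p = 0.265 over all genes), beside the fall of Cxcl10 and Ccl12. Nucleic acid sensing and interferon signalling genes had a median of -0.36 over 19 tested members (camera adjusted p = 0.013; adjusted p = 0.717 with an estimated correlation), and none was called over all genes or adjusted over the list alone (2 had an unadjusted limma p under 0.05). Tlr9, an endosomal DNA sensor, had a log2 fold change of -1.03 ± 0.27 (adjusted p = 0.313), and Tlr7, an endosomal RNA sensor, one of -0.75 ± 0.33 (adjusted p = 0.556). With knockout replicate 2 left out, Tlr9 was at -0.91 ± 0.27 and Tlr7 at -0.38 ± 0.19. This list stood at -0.997 in knockout replicate 2 and at -0.02 and -0.09 in knockout replicates 1 and 3. It was not called without knockout replicate 2 (median -0.09, adjusted p = 0.0511), where Irf3 itself fell adjusted over the list alone (-0.72 ± 0.14, adjusted p = 0.109 over all genes), or without wild-type replicate 1 (median -0.34, adjusted p = 0.123).

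Macrophage genes were low in 1 knockout library. The median of the 30 tested monocyte and macrophage genes was -1.46 in knockout replicate 2 relative to the wild-type mean, against 0.12 and -0.15 in knockout replicates 1 and 3 and 0.50, -0.22 and -0.26 in the wild type. Over all libraries the list was called (median -0.44, camera adjusted p = 0.0273; adjusted p = 0.879 with an estimated correlation). It was not called without knockout replicate 2 (median -0.02, adjusted p = 0.505) or without wild-type replicate 1 (median -0.13, adjusted p = 0.652). Of its members Apoe, which encodes the lipid carrier apolipoprotein E, fell 5.85-fold, from 2020 ± 815 to 345 ± 84.5 RPKM (SD, n = 3 per group; limma adjusted p = 0.0403), and adjusted over the list alone Apoe, Plac8 and Ly6c2 fell. Without knockout replicate 2 no member was called over all genes, and Apoe and Plac8 fell adjusted over the list alone. Apoe lost its call over all genes in each of the 6 fits that left out a library. Plac8 and Ly6c2, markers of inflammatory monocytes, had log2 fold changes of -1.31 ± 0.22 and -1.38 ± 0.32 (adjusted p = 0.0625 and 0.203 over all genes). The abundant macrophage transcripts Lyz2 and Cd68 had log2 fold changes of -0.07 ± 0.64 and 0.29 ± 0.39 (adjusted p = 0.957 and 0.72). Neutrophil genes (8 tested, median -0.24, camera adjusted p = 0.561) and dendritic cell genes (8 tested, median -0.16, adjusted p = 0.851) were not called, and neither list had a member called over all genes or adjusted over the list alone (0 and 1 had an unadjusted limma p under 0.05). Csf3r and Retnlg of the neutrophil list were at -0.63 ± 0.34 and -0.96 ± 0.52, and Clec9a of the dendritic list was at -0.48 ± 0.19 (adjusted p = 0.556 for all of these). Siglece, Itgax and Ccr7 were at -0.24 ± 0.19, 0.61 ± 0.45 and -0.20 ± 0.21 (adjusted p = 0.578, 0.571 and 0.657). The lymphocyte list had 4 tested members, too few for its test, and none of them was called over all genes or adjusted over the list alone (2 had an unadjusted limma p under 0.05); their median was -0.44.

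Genes of fibroblasts and the extracellular matrix were lower as a list. Their median log2 fold change was -0.49 over 36 tested genes, 35 of them with a value below 0 (camera adjusted p = 1.36e-06; adjusted p = 0.717 with an estimated correlation). No member was called over all genes or adjusted over the list alone (8 had an unadjusted limma p under 0.05). Col8a1, a short-chain collagen, stood at 64.2 ± 13.3 against 151 ± 48.4 RPKM (SD, n = 3 per group; limma adjusted p = 0.204), and Lox, which crosslinks collagen, at 76.3 ± 16.5 against 146 ± 27.1 RPKM (adjusted p = 0.339). Cthrc1, a marker of activated fibroblasts, was at 98.1 ± 11.4 against 181 ± 43.1 RPKM (adjusted p = 0.368). The list stood at -0.39, -0.91 and -0.27 in knockout replicates 1 to 3, where cardiomyocyte genes stood at 0.36, 1.09 and 0.54. Without replicate 2 the median of the fibroblast list was -0.35 (camera adjusted p = 1.17e-06, and 0.711 with an estimated correlation). Matrix metalloproteinases and their inhibitors were not called as a list (22 tested, median -0.20, adjusted p = 0.629). Mmp2, a gelatinase of fibroblasts, was at 56.2 ± 7.98 against 123.4 ± 7.32 RPKM, a log2 fold change of -1.13 ± 0.20 (limma adjusted p = 0.0761), and was the only gene to fall adjusted over the list alone. Mmp9, the gelatinase of neutrophils and macrophages, had a log2 fold change of 1.52 ± 0.46 (adjusted p = 0.434), and Timp3 one of -0.75 ± 0.27 (adjusted p = 0.537). Mesothelial and epicardial genes had a median of -0.80 with all 12 values below 0 (camera adjusted p = 7.72e-04; adjusted p = 0.717 with an estimated correlation), and none was called over all genes or adjusted over the list alone (4 had an unadjusted limma p under 0.05). Msln was at 13.4 ± 5.90 against 39.5 ± 26.6 RPKM, Muc16 at 0.980 ± 0.966 against 4.63 ± 3.51 RPKM and Krt18 at 6.74 ± 2.18 against 12.5 ± 4.35 RPKM (adjusted p = 0.556 for each). The mesothelial list varied widely within groups, from -0.74 to 0.74 among wild-type libraries and from -1.52 in knockout replicate 2 to -0.33 in replicate 1. Its median was -0.52 without knockout replicate 2 (camera adjusted p = 0.00356, and 0.949 with an estimated correlation) and -0.54 without wild-type replicate 1 (camera adjusted p = 0.0231).

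Endothelial genes (21 tested, median -0.06, camera adjusted p = 0.827) and smooth muscle and pericyte genes (14 tested, median -0.04, adjusted p = 0.851) were not called. Relative to the rest of the transcriptome camera placed both lists, and that of the cell cycle (30 tested, median -0.04, adjusted p = 0.851), higher in the knockout, although their medians and means were below 0. The median of all genes was -0.09. Esm1, Cd36 and Tek of the endothelial list had log2 fold changes of -0.94 ± 0.26, 0.46 ± 0.26 and -0.62 ± 0.38 (limma adjusted p = 0.344, 0.556 and 0.556). Myh11, Rgs5 and Des of the smooth muscle list were at -0.50 ± 0.28, -0.57 ± 0.45 and 0.63 ± 0.51 (adjusted p = 0.556, 0.578 and 0.584). Cenpf, Mcm5 and Kif11 of the cell cycle list were at -0.88 ± 0.39, 0.48 ± 0.25 and -0.68 ± 0.39 (adjusted p = 0.556 each). With knockout replicate 2 left out, Esm1, Cd36 and Tek were at -0.75, 0.46 and -0.13. Myh11, Rgs5 and Des were then at -0.22, -0.11 and 0.18, and Cenpf, Mcm5 and Kif11 at -0.39, 0.48 and -0.22. Without knockout replicate 2, where the cell cycle list stood at -0.51, its median was 0.16 (camera adjusted p = 0.0496; adjusted p = 0.949 with an estimated correlation). None of these 3 lists had a member called over all genes or adjusted over the list alone; 1 endothelial gene and 0 of the others had an unadjusted limma p under 0.05.

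Cardiomyocyte genes and genes of mitochondrial energy metabolism were higher as lists. The 30 cardiomyocyte genes had a median log2 fold change of 0.60, 27 of them with a value above 0 (camera adjusted p = 1.36e-06; adjusted p = 0.717 with an estimated correlation). The 29 tested genes of fatty acid oxidation and oxidative phosphorylation had a median of 0.52 (camera adjusted p = 6.93e-08; adjusted p = 0.717 with an estimated correlation). No member of either list was called over all genes or adjusted over the list alone (4 and 3 had an unadjusted limma p under 0.05). Ckm, the muscle creatine kinase, was at 588 ± 366 against 180 ± 105 RPKM (SD, n = 3 per group; limma adjusted p = 0.454), and Myh7, the slow myosin heavy chain, at 99.1 ± 62.0 against 38.4 ± 25.3 RPKM (adjusted p = 0.556). Tcap, a protein of the Z-disc, had a log2 fold change of 1.38 ± 0.56 (adjusted p = 0.556). Ucp3, Ndufb8 and Etfb of the metabolic list had log2 fold changes of 1.02 ± 0.38, 0.69 ± 0.29 and 0.65 ± 0.28 (adjusted p = 0.556 each). The cardiomyocyte list spread as widely within groups as between them: it stood at -0.79, 0.17 and 0.70 in wild-type replicates 1 to 3 and at 0.36, 1.09 and 0.54 in knockout replicates 1 to 3, and the metabolic list at -0.56, -0.0039 and 0.52 against 0.31, 0.63 and 0.36. Without wild-type replicate 1 the cardiomyocyte list was not called (median 0.18, adjusted p = 0.149) and the metabolic list had a median of 0.28 (adjusted p = 0.0176). Without knockout replicate 2 their medians were 0.43 (camera adjusted p = 0.00211) and 0.37 (camera adjusted p = 1.05e-04). With an estimated correlation the adjusted p of camera was then 0.949 for each.

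Hypoxia and glycolysis genes differed little, with a median of 0.11 over 22 tested genes (camera adjusted p = 0.0385; adjusted p = 0.661 with an estimated correlation) that was -0.17 with the libraries scaled to equal sums, a scaling that put the median of all genes at -0.38. Egln3 and Ankrd37, both induced by hypoxia, had log2 fold changes of 1.09 ± 0.38 and 0.49 ± 0.19 (limma adjusted p = 0.519 and 0.556), and P4ha1 one of -0.65 ± 0.28 (adjusted p = 0.556). The hypoxia list was not called without knockout replicate 2 (adjusted p = 0.114), without knockout replicate 3 (adjusted p = 0.0779) or without wild-type replicate 1 (adjusted p = 0.36). Red cell and platelet genes had a median of 0.98 over 8 tested members (camera adjusted p = 0.0024; adjusted p = 0.717 with an estimated correlation), with values of 2.05, 1.04 and -0.42 in knockout replicates 1 to 3 and 0.97, -0.64 and -0.18 in the wild type. Alas2 was at 16.4 ± 11.4 against 4.52 ± 3.23 RPKM and Hba-a1 at 93.2 ± 65.4 against 31.5 ± 25.9 RPKM, and Hba-a2 at 32.7 ± 23.1 against 11.8 ± 8.81 RPKM (SD, n = 3 per group; limma adjusted p = 0.556 each). The list was not called without knockout replicate 1 (median 0.34, adjusted p = 0.0695) or without knockout replicate 2 (median 0.82, adjusted p = 0.0511). Neither list had a member called over all genes or adjusted over the list alone; 3 hypoxia genes and 0 red cell genes had an unadjusted limma p under 0.05. Immediate early and stress genes (20 tested, median 0.15, adjusted p = 0.181) were not called, with Dusp1 at 0.57 ± 0.19, Ddit3 at -0.77 ± 0.27 and Hspa1b at -0.44 ± 0.22 (adjusted p = 0.513, 0.52 and 0.556), and no member called over all genes or adjusted over the list alone; without knockout replicate 1 the median was 0.26 (adjusted p = 0.0153). Skeletal muscle genes (6 tested, median -0.39, adjusted p = 0.851) were not called. Adjusted over that list alone Tnnt3, Tnni2 and Mylpf fell while Ckm and Eno3, both also expressed in heart muscle, rose, and without knockout replicate 2 no member passed. Adipocyte genes (5 tested, median 0.11, adjusted p = 0.723) were not called, with Acaca at -0.26 ± 0.24, Lpl at 0.26 ± 0.40 and Pparg at 0.11 ± 0.34 (adjusted p = 0.616, 0.761 and 0.881). No adipocyte gene was called over all genes or adjusted over the list alone, though without knockout replicate 2 Pparg rose adjusted over the list alone (0.53 ± 0.12, adjusted p = 0.228 over all genes), and Lpl was at -0.05 and Pparg at -0.17 with equal library sums.

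**Figure D2:**
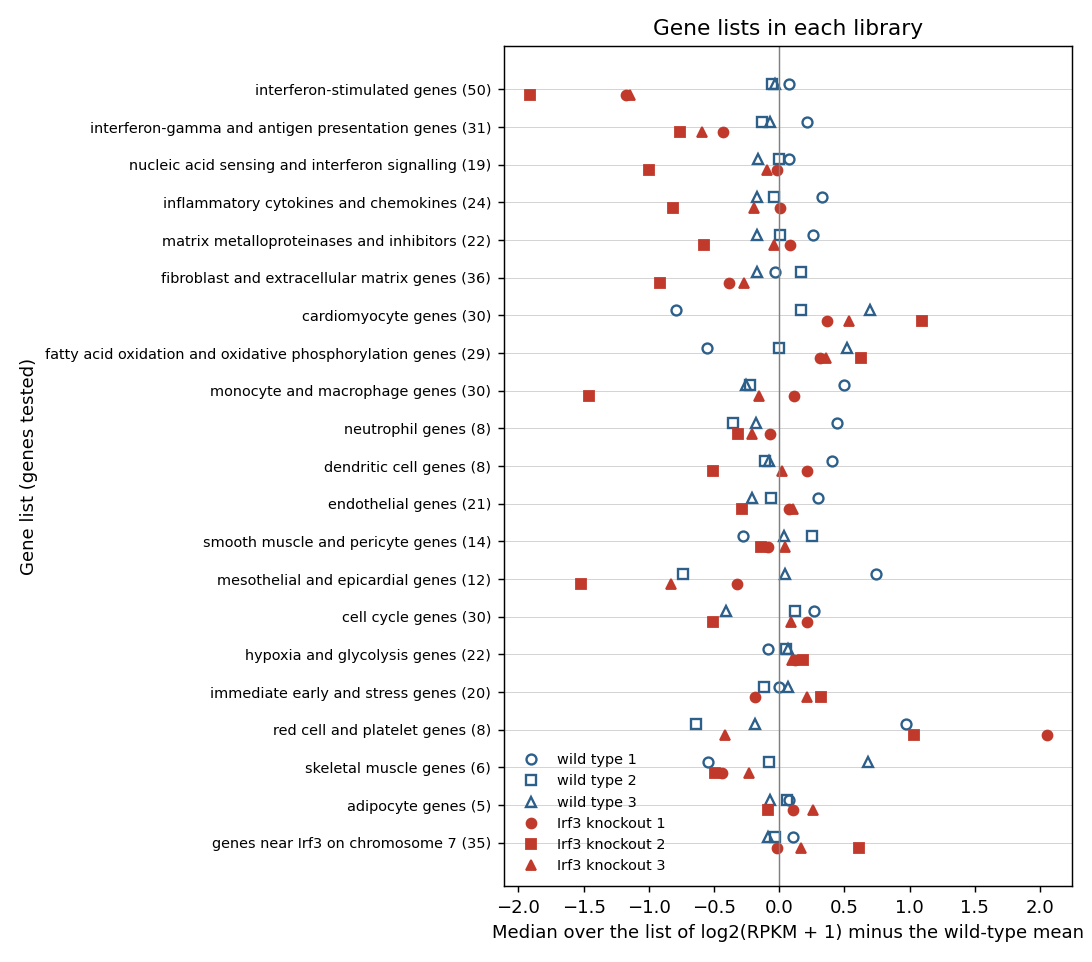
Median over each of 21 gene lists of log2(RPKM + 1) minus the wild-type mean, for each library, with open blue symbols for wild type and filled red symbols for the Irf3 knockout and the number of genes tested in brackets. Interferon-stimulated genes stand at -1.18, -1.91 and -1.14 in the knockout libraries, while macrophage genes stand at -1.46 in knockout replicate 2 and at 0.12 and -0.15 in the other knockout libraries.

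Across all genes, 65 of 12913 passed the test, 19 higher and 46 lower in the knockout, and 1085 had an unadjusted p under 0.05. Every one of the 65 had its knockout libraries all on one side of its wild-type libraries, as had 18.4% of all tested genes, where chance gives 10%. Without knockout replicate 2 the test called 96 genes, 27 higher and 69 lower, 58 of them shared with the 65. Camera called 12 of the 21 lists over all libraries, and 7 without knockout replicate 2 or without wild-type replicate 1. The count of called genes was 26 without knockout replicate 3 and 31, 30 and 21 without wild-type replicates 1 to 3, and 20 of the 65 genes were called whichever library was left out.

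Outside the interferon lists, 19 genes rose and 26 fell (27 and 36 without knockout replicate 2), and the largest changes were in ribosomal protein genes and pseudogenes that nearly vanished from one genotype. The 26 still include genes that interferon induces but the interferon lists do not hold, among them Cxcl10, Gm4951 and Gm12250. The counts of copies and of chromosome 7 genes below start from this mixed set. Rps13-ps1 stood at 149 ± 32.7 RPKM in the knockout and 0.110 ± 0.105 in the wild type (SD, n = 3 per group; log2 fold change 7.06 ± 0.21, limma adjusted p = 4.05e-06). Gm10159, whose transcript matches that of Rps13-ps1 at 99.6% identity, stood at 0.010 ± 0.017 against 87.5 ± 18.01 RPKM (adjusted p = 4.05e-06). Rpl29 fell from 86.2 ± 17.0 to 0.720 ± 0.416 RPKM (adjusted p = 4.41e-05) while its copy Gm8210 rose from 2.03 ± 0.681 to 40.1 ± 8.80 RPKM (adjusted p = 3.54e-04). Rps3a fell from 114 ± 18.1 to 4.08 ± 0.90 RPKM (adjusted p = 5.36e-05) while its copy Gm9000 rose from 12.9 ± 1.45 to 229 ± 26.3 RPKM (adjusted p = 5.36e-05). Added over both members in CPM (RPKM times gene length in kb), Rps13-ps1 and Gm10159 came to 68.1 ± 14.9 in the knockout and 45.6 ± 9.40 in the wild type (SD, n = 3), with overlapping libraries, so the separate values of such genes are uncertain. Rps3a with its 3 copies came to 244 ± 22.8 against 159 ± 24.6 CPM, while the 3 copies of Rpl29 together held 19.5 ± 4.24 against 8.22 ± 0.98, less than the 68.6 that Rpl29 itself held in the wild type. Of the 43 called genes outside the interferon lists with a transcript to search, 17 matched another gene of the table at 95% identity or more over at least 200 bases, against 61 of 500 genes drawn at random from those not called (Fisher's exact test, two-sided, p = 1.81e-05). Some of the 17 are copies of each other, and they form 13 families, so this test counts genes that are not independent. They include I830012O16Rik, which matches Ifit3, and Arg2, whose transcript overlaps that of Vti1b.

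**Figure D3:**
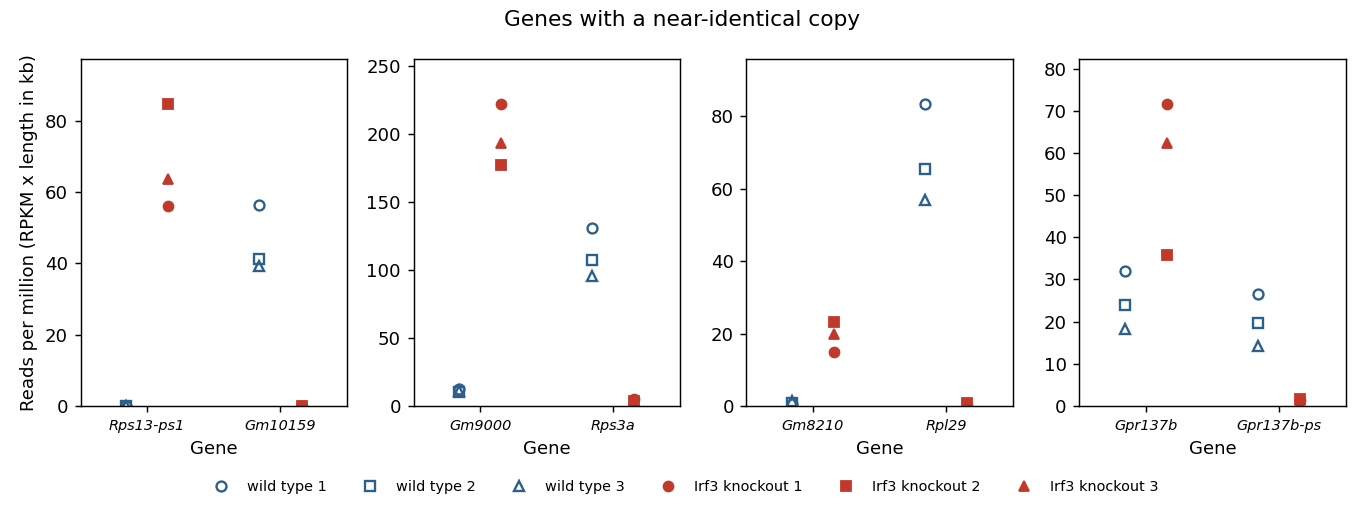
CPM (RPKM times gene length in kb) of 4 pairs of genes with near-identical transcripts in each library, with open blue symbols for wild type and filled red symbols for the Irf3 knockout and each panel on its own axis from 0. Within each pair the gene on the right is lower in all knockout libraries than in all wild-type libraries, and the gene on the left is higher in all knockout libraries than in all wild-type libraries. The 4 pairs were chosen after their values were seen. Of the 13 families of copies among called genes outside the interferon lists, 7 had copies that moved against the gene.

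Other genes that changed were present in both genotypes. Hddc3, a ppGpp hydrolase, rose 6.99-fold, from 5.11 ± 0.64 to 35.8 ± 2.47 RPKM (SD, n = 3 per group; limma adjusted p = 4.82e-04). Kcnj14, an inward-rectifier potassium channel, rose 6.76-fold (adjusted p = 0.0268), Arg2, the mitochondrial arginase, rose 5.88-fold (adjusted p = 0.0449), and Hdhd3, Morn4 and Rplp0-ps1 rose 3.32-fold, 3.02-fold and 3.09-fold (adjusted p = 0.033, 0.0329 and 0.0268). The Arg2 transcript overlaps that of Vti1b, so reads of the latter can be counted in it. Rplp0-ps1 is by its symbol a pseudogene of Rplp0. It is not among the 17 genes with a match, and whether reads of Rplp0 are counted in it was not tested. Besides Apoe, Apoc2, which encodes the activator of lipoprotein lipase, fell 10.4-fold, from 15.5 ± 9.20 to 1.5 ± 0.77 RPKM (adjusted p = 0.033; 6.81-fold without wild-type replicate 1). Thbs4, a matricellular thrombospondin, fell 6.52-fold, from 48.2 ± 20.9 to 7.4 ± 1.98 RPKM (adjusted p = 0.0306), and Ogdhl fell 12.1-fold (adjusted p = 0.0416; 22.5-fold without knockout replicate 2). Hddc3, Rps13-ps1, Rpl29 and Rps3a were called whichever library was left out; the highest adjusted p was 0.156 for Kcnj14, 0.247 for Arg2, 0.211 for Hdhd3, 0.168 for Rplp0-ps1, Ogdhl and Thbs4 and 0.11 for Apoc2, all without wild-type replicate 3, 0.27 for Morn4 without wild-type replicate 2 and 0.172 for Apoe without knockout replicate 3. Of the 41 called genes outside the interferon lists with a known chromosome, 8 (19.5%), Apoe, Apoc2, Hddc3 and Kcnj14 among them, lie on chromosome 7, which also carries Irf3.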

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

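The tests with limma-voom, the correction for GC content and length, and array weights on other splits were chosen after the result was seen; the others were planned. All 65 calls kept their sign with each library left out. Since the groups of all 65 do not overlap, this was fixed in advance and says nothing of their stability. The list of interferon-stimulated genes stayed lower in every fit run, called by camera at the preset correlation in each, with medians from -1.51 to -1.11 over the fits that left out a library. Lists called numbered 12, and 0 with an estimated correlation, 0 with fry, 7 with array weights and 6 with limma-voom without knockout replicate 2. The cause of the changes given here was not tested, except that fewer genes or libraries enter some fits. Whole reads could not be recovered for all genes from values rounded to 2 decimals, so the planned negative binomial count tests were not run, and TMM factors were not used, the median of ratios taking their place. In the other 9 splits of the libraries camera called 3 to 15 lists, so 12 called lists is not more than other groupings gave; the size of the interferon-stimulated median was 1.36 in the real split and 0.67 at most in the others, and 10 splits are too few for a share under 0.05. Except for interferon-gamma, fibroblast and near-Irf3 genes, each other called list had a larger size in at least 1 other split. The highest other was 0.76 against 0.44 (macrophage), 0.83 against 0.60 (cardiomyocyte), 0.61 against 0.52 (fatty acid oxidation), 1.19 against 0.80 (mesothelial), 1.98 against 0.98 (red cell), 0.46 against 0.35 (cytokine), 0.44 against 0.36 (nucleic acid sensing) and 0.16 against 0.11 (hypoxia).

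The count of called genes, 65 as reported, was 34 with a mean of at least 5 RPKM, 104 with quantile normalization, 36 with equal library sums (which put the median of all genes at -0.38), 2960 with array weights (0 in the other splits but 1, which gave 248), 120 with limma-voom without knockout replicate 2, 118 after the GC and length correction and 111 at a threshold of 0.1. The array weights were 6.36 for knockout replicate 3 and 4.4 for wild-type replicate 2, against 0.103 to 1 for the others. That fit thus rests mostly on those libraries. With the replicate block the count was 250, all 65 among them; the block left hypoxia genes at 0.11 without their call and turned the camera direction of cell cycle (-0.039) and dendritic cell genes (-0.16). Deviations of same-numbered libraries correlated at 0.129, -0.098 and -0.102, and not every library correlated best with its own number. The labels do not say that a number is shared. A pairing was neither shown nor excluded.

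Medians of lists that lost or gained a call, or whose camera direction turned, are given with the list in brackets, beside named genes that turned. With array weights they were -0.094 (nucleic acid sensing), -0.15 (cytokine), -0.017 (metalloproteinase), 0.045 (macrophage), 0.086 (neutrophil), 0.084 (dendritic cell), -0.089 (smooth muscle), -0.23 (mesothelial), 0.10 (hypoxia), 0.22 (stress), 0.64 (red cell) and -0.21 (skeletal muscle), and Ccr7 was at 0.11. With limma-voom without knockout replicate 2 they were -0.091 (nucleic acid sensing), -0.13 (cytokine), 0.039 (metalloproteinase), 0.036 (macrophage), 0.023 (dendritic cell), -0.034 (smooth muscle), 0.12 (hypoxia), 0.61 (red cell) and 0.065 (near-Irf3), and Ccr7 was at 0.018. With limma-voom on all libraries they were -0.38 (cytokine). With a mean of at least 5 RPKM they were -0.28 (cytokine), -0.010 (smooth muscle), -0.016 (cell cycle) and 0.073 (hypoxia). With quantile normalization they were 0.037 (dendritic cell), -0.047 (endothelial), 0.014 (smooth muscle), 0.13 (hypoxia) and 0.24 (near-Irf3), and Ccr7 was at 0.013. With equal library sums they were -0.44 (dendritic cell), -0.36 (endothelial) and -0.71 (skeletal muscle), and Lpl was at -0.052 and Pparg was at -0.17. After the GC and length correction they were -0.058 (smooth muscle), 0.19 (hypoxia), -0.0089 (stress), 0.74 (red cell) and 0.13 (near-Irf3), and Acaca was at 0.012.

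Leaving out each library in turn gave 21 to 96 called genes and 7 to 12 called lists. The value of Ccr7 ranged over -0.30 to -0.0078 in these fits, and that of Acaca over -0.40 to -0.0027. Medians, and the values of Lpl and Pparg, then ranged over -0.57 to -0.091 (nucleic acid sensing), -0.53 to -0.088 (cytokine), -0.32 to 0.042 (metalloproteinase), 0.18 to 0.96 (cardiomyocyte), -0.81 to -0.020 (macrophage), -0.42 to -0.090 (neutrophil), -0.26 to 0.056 (dendritic cell), -0.11 to 0.16 (endothelial), -0.10 to 0.058 (smooth muscle), -0.25 to 0.16 (cell cycle), 0.10 to 0.16 (hypoxia), 0.014 to 0.26 (stress), 0.34 to 1.71 (red cell), -0.56 to -0.16 (skeletal muscle), -0.15 to 0.11 (adipocyte), 0.063 to 0.40 (near-Irf3), -0.15 to 0.61 (Lpl) and -0.12 to 0.53 (Pparg).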

Other observations

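Tests of macrophage content, of knockout replicate 2 alone, of its depth and myocardium, of the longer chromosome 7 segment, of every family of copies and of the GC and length correction as the whole cause were chosen after the result was seen; those of copies, of the segment near Irf3, of GC content and of the other splits were written before it. The genes named here were chosen after their values were seen. Genes outside the fixed lists also fell. Slfn4, a Schlafen gene of myeloid cells, fell 13.0-fold, from 6.45 ± 1.25 to 0.497 ± 0.314 RPKM (SD, n = 3 per group; limma adjusted p = 0.00367). Gm4951 and Gm12250, interferon-inducible GTPases, fell 14.6-fold and 4.51-fold (adjusted p = 0.0125 and 0.0366). Leaving out 1 library at a time, Gm4951 lost its call in 3 of 6 fits and Gm12250 in 5 (adjusted p up to 0.0824 and 0.211, without wild-type replicate 3). Pydc4, a pyrin-domain gene, fell 14.0-fold (adjusted p = 0.00926) and lost its call in 3 of these fits (adjusted p up to 0.0774, without wild-type replicate 3), and I830012O16Rik fell 6.61-fold (adjusted p = 0.00367), although its transcript matches that of Ifit3 at 97.8% identity and its reads are uncertain.

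Gpr77, the second receptor of C5a, fell 7.37-fold, from 3.29 ± 1.21 to 0.447 ± 0.078 RPKM (SD, n = 3 per group; limma adjusted p = 0.0336). It lost its call in 5 of the 6 fits that left out a library (adjusted p up to 0.151, without wild-type replicate 2). Its neighbour C5ar1 was at 22.8 ± 7.996 against 57.7 ± 23.8 RPKM (adjusted p = 0.329). Apoc1, which lies between Apoe and Apoc2, was at 4.55 ± 0.936 against 1.71 ± 1.12 RPKM (adjusted p = 0.434).

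Interferon-stimulated genes were lower in all 3 knockout libraries. Fewer macrophages in the knockout samples would lower the macrophage list too, yet the lower of its medians in knockout replicates 1 and 3 was -0.15 while the interferon-stimulated list stood at -1.18 and -1.14 there. Without knockout replicate 2 the interferon-stimulated list kept a median of -1.11. Both argue against fewer macrophages in general, and against that library alone, as the whole cause. A list median cannot show the loss of a subset, which was not tested. Plac8 and Ly6c2, markers of inflammatory monocytes, were lower in all 3 knockout libraries than in any wild-type library. Of the 30 macrophage genes 23 had a log2 fold change below 0 and 7 above. Within knockout replicate 2, where the macrophage list stood at -1.46 (quartiles -1.73 to -0.567), a smaller macrophage share may contribute to the lower value of -1.91. After the correction for GC content and length these values were -0.99 and -1.50. The drop there was not particular to macrophage genes. Mesothelial, nucleic acid sensing and fibroblast lists stood at -1.52, -0.997 and -0.91 in that library before the correction, and cardiomyocyte genes at 1.09. Over genes, 1 of the 10 splits of the 6 libraries, the real one, gave as many as 65 calls and the highest other gave 0, and 10 splits are too few for a share under 0.05. Loss of Irf3 itself, which the design names, remains among the open explanations.

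Called genes outside the interferon lists held many members of families of near-identical copies and 8 genes of chromosome 7. Summed over each of the 17 called genes and its copies, the median absolute log2 ratio was 0.623 against 3.70 for the genes alone (0.577 against 2.67 with each of the 13 families counted once). This met the value set beforehand for reads moved between copies by variants of the strain. In 8 of the families, however, the copies outweigh the gene so that the sum moves little by construction, and over all families this cannot be told apart. The copies did not outweigh Rps13-ps1 and Gm9000, whose log2 ratios of 8.83 and 4.14 became 0.577 and 0.623 in the sums. There most of the change lay in which copy held the reads, and its cause was not tested. Nor did copies outweigh Rpl29, Gm13157 and Capza1, whose sums kept log2 ratios of -1.935, -1.95 and -0.97. The copies of Gm13157 and Gm13453 moved the same way as the gene with no overlap between groups. I830012O16Rik moved so too, but its only copy, Ifit3, is on the interferon-stimulated list. That family therefore does not bear on whether reads moved between copies in every family. The bound of 3 such families, set with these values already seen, was met only with it, so this test cannot decide. Copies that the table does not hold were not searched. In 7 of the 13 families the copies moved against the gene (exact binomial test, one-sided, p = 0.5). Of these genes 19.5% (exact 95% interval 8.8% to 34.9%) lie on chromosome 7. A segment of that chromosome that came with Irf3 therefore cannot account for all of them by acting on the genes it holds. Whether such a segment acts on genes elsewhere was not tested. Gm10159, for example, lies on chromosome 7 and its copy Rps13-ps1 on chromosome 8. Within 200 genes of Irf3 lay 1 of 41 against 103 of 12591 other genes (Fisher's exact test, one-sided, p = 0.288), too few to decide. Over the whole chromosome it was 8 of 41 against 943 of 12591 (Fisher's exact test, one-sided, p = 0.0103), but 3 of 18 loci without copies and with called genes up to 200 genes apart counted once (exact binomial test, one-sided, p = 0.15), so a longer segment, which would have to reach from Irf3 over 785 genes to Hddc3 or to Apoe at -1007 and Apoc2 at -1011 genes, stays open for part of them.

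Knockout replicate 2 stood apart from the other libraries. Its depth of 18.1 M reads lay inside the range of the others, which argues against depth. Across genes its deviation followed GC content with a Spearman rho of 0.562 and length with one of -0.329 (genes are not independent replicates). A GC or length bias may therefore contribute. Knockout replicate 1, which did not stand apart, had a GC rho of -0.562. Each deviation was taken from the mean of the other 5 libraries, so the rho of replicate 1 is not independent of replicate 2. After correction for GC content and length the mean correlation of replicate 2 with the others was 0.931, still the lowest. This argues against such a bias as the whole cause. More surviving myocardium would lower the lists of all other cell types alike; their medians there spread over 1.38, but over 1.02 in wild-type replicate 1, which did not stand apart, so this cannot be told apart as the whole cause. Batch, RNA quality and other biological explanations were not tested.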
